A study of Mus musculus and Mus spretus with 18 samples.

How the data were processed

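Expression was measured in whole brain, without the olfactory bulb, of male mice of 2 species at 3 ages. Total RNA of each brain was labelled with biotin and hybridised to an Affymetrix mouse genome array, per the labels' protocols. The array is of the 1-colour type, so each array carries the RNA of 1 sample. The labels describe each sample as an individual, and 6 groups of 3 arrays were formed from the species and age given in the sample titles. No processing date or batch was given in the sources used here, so no batch could be examined.

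The deposited table gave 1 value per Ensembl gene and array, for 12346 genes and 18 arrays, with no missing value. The deposited values are on a log2 scale. The log base was inferred from the values, which ran from 2.89 to 13.82: as powers of 2 the top value is 14485, which a 16-bit scanner can record, and as powers of e it would be 1006760, which it cannot. The table was already normalized between arrays when the authors deposited it, since the array medians lay between 6.52 and 6.56. The method of background correction, summarisation and normalization and any filter on genes are not given in the sources used here. The values were used as deposited.

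The second deposited table was a list of probes that the authors masked, with the probe set and the position on the array. The reason for masking is not stated in the sources used here, and neither is the number of probes kept per gene. The name of the list holds the word mussprmask, which may stand for the 2 species, but it is not explained. The list held 46864 probes, of which 45770 belonged to gene probe sets and 1094 to control probe sets. Of the 12346 genes with values, 9125 had at least 1 masked probe, with a median of 2 and a maximum of 72, and 3221 had none. The list was therefore read as probes removed, not probes kept. It was used only to count masked probes per gene.

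The files do not pair the Ensembl IDs with gene names. The reference table given for this series held 49997 genes and no Ensembl ID, so 0 of the 12346 IDs could be matched to a symbol. The 27 gene lists of brain cell types and pathways fixed before the data were examined had 0 members that could be matched, and their set tests were not run. The rule fixed for naming genes took those with the largest log2 change in each direction, past the threshold and, outside the tests of a difference in change, without overlap between the groups' values. It was applied to IDs in place of symbols and shortened to 2 IDs per direction, in musculus for the age comparisons and over all 3 ages for the species comparison.

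Tests were fitted with limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 6 groups was fitted to all 18 arrays (lmFit), contrasts were taken from it (contrasts.fit) and the variances were moderated across genes (eBayes). The model left 12 residual degrees of freedom, 17.1 after moderation. P-values were adjusted by the method of Benjamini and Hochberg within each comparison over all 12346 genes, and a gene was called at an adjusted p under 0.05. All limma tests were two-sided. The comparisons were day 14 minus day 0 and day 56 minus day 14 within each species, spretus minus musculus at each age, the genes called between the species at all 3 ages with 1 sign, and for each age step the spretus change minus the musculus change. This last contrast is the test of a difference in change between the species. The number of genes that 2 or 3 independent lists of the observed lengths would share is given beside most overlaps of lists that share no array.

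The place of each day 14 array between day 0 and day 56 was computed as a percent. Genes called from day 0 to day 56 in both species with 1 sign and at least 2-fold were taken. For each of them the day 14 value minus the day 0 mean of its own species was divided by the day 56 mean minus the day 0 mean, and the median over genes was taken per array. The 3 arrays of each species were compared by a two-sided exact permutation test, whose smallest p is 0.1. Root mean square changes over genes had the variance expected from the replicates subtracted. Correlations across genes describe the likeness of profiles and have no p-value, since genes are not independent replicates.

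The limma procedure was tested on simulated data made from the observed gene means and replicate spreads over all 12346 genes, with 50 genes changed at each of several sizes. For day 14 against day 0 in musculus, 62% of genes changed by 0.5 on the log2 scale and 96% of those changed by 1 were recovered. For the difference in change over the same step, 26% of genes changed by 0.5 and 90% of those changed by 1 were recovered. The adjusted threshold depends on how many genes change, and 5110 genes were called in the data for the first of these comparisons. The recovered shares thus hold for the simulated setting alone. False calls made up 3.57% of calls in the first simulation and 6.09% in the second. They were above 5% in others too, with the highest shares at 8.90% for day 56 against day 14 in musculus and 7.83% for the difference in change from day 14 to day 56.

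Alternatives fixed before the data were examined were a repeated quantile normalization, centring each array on its median, leaving out the 25% of genes with the lowest mean, an intensity trend with a robust prior, a fit on the arrays of the contrast alone, genes with no masked probe alone, the replicate number as a block, and leaving out each array in turn. Leaving out genes with 7 or more masked probes was added after the data were seen, and so was, for the genes called at all 3 ages, centring each array on the genes with 0 or 1 masked probe within 4 strata of expression level. For the place of the day 14 arrays, other fold limits (4 and 1.5), the direction of change and reference means over both species were varied as well. For the count of called genes in each comparison, other splits of the same arrays were run. Array number sets the precision: with 3 arrays per group the median standard deviation between replicates was 0.14 on the log2 scale.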

Results

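Gene expression was profiled in the brains of 18 male mice across postnatal development. The animals came from 2 species, Mus musculus (the wild-derived inbred strain WSB/EiJ) and Mus spretus (the wild-derived inbred strain SPRET/EiJ), called musculus and spretus from here on. Brains were taken without the olfactory bulb on the day of birth (day 0), from pups at day 14 and from young adults at day 56. Each of the 6 groups held 3 animals with 1 array each. Log2 expression values were given for 12346 Ensembl genes. Because the files do not pair these IDs with gene names, genes are described as groups that share a time course or a direction, and at most 2 IDs per direction are given as examples of a comparison.

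Over all genes, age was the main source of variation, and species came next. Among genes with no masked probe, species calls did not outnumber those from day 14 to day 56 at every age, as given further on. The first principal component held 64.2% of the variance and followed age, with a mean score in musculus of -45.7 ± 2.43 at day 0, 15.6 ± 2.59 at day 14 and 26.5 ± 0.0833 at day 56 (SD, n = 3). The spretus arrays had mean scores of -40.1 ± 0.903, 18.3 ± 0.470 and 25.4 ± 0.671 at the same ages. The second component, with 10.8% of the variance, parted the species at every age, and its group means were 11.3 to 13.4 in musculus and -13.1 to -11.8 in spretus. The third component, with 5.68%, ran from day 14, with group means of -12.9 in musculus and -10.0 in spretus, to day 56, with 9.64 and 10.5, and day 0 lay between them, at 4.38 and -1.61. Across genes, arrays of 1 group correlated with a median r of 0.994, arrays of the same age from the other species with 0.988, days 14 and 56 within a species with 0.990, and days 0 and 56 within a species with 0.953.

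**Figure D1:**
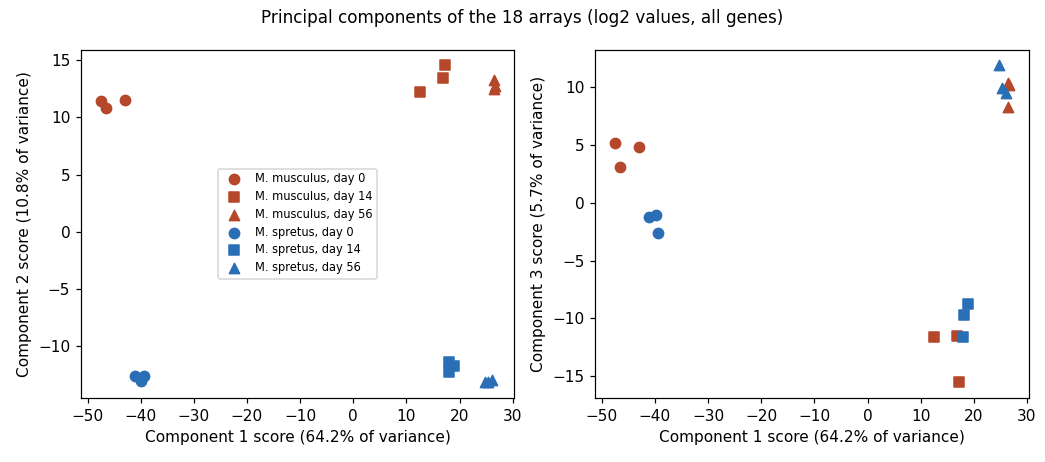
Scores of the 18 arrays on component 1 (horizontal axes) against component 2 (left) and component 3 (right), in arbitrary units of the log2 values; each point is an array, colour gives the species and shape the age. Component 1 orders the ages from day 0 to day 56 and component 2 separates all musculus arrays from all spretus arrays.

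Between birth and day 14 a large part of the brain transcriptome changed, and it changed alike in both species. In musculus 2416 genes rose and 2694 fell, together 41.4% of the genes tested, and 521 of the rising and 425 of the falling genes changed at least 2-fold. In spretus 2369 genes rose and 2508 fell, or 39.5%, with 436 and 382 changed at least 2-fold. The risen genes had a median log2 change of 0.58 in musculus and 0.55 in spretus, and the fallen genes of -0.54 in both. The species shared 1782 rising and 2029 falling genes, where independent lists of these lengths would share 464 and 547. Only 16 genes were called in opposite directions, against 1008 for independent lists.

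The genes with the largest changes rose or fell by similar amounts in spretus, with 1 exception. ENSMUSG00000027375 rose in musculus from 4.99 ± 0.23 at day 0 to 11.33 ± 0.29 at day 14 (log2, SD, n = 3), a change of 6.35 ± 0.15 (SE; limma, adjusted p = 1.85e-14), and by 5.92 ± 0.15 in spretus (adjusted p = 3.03e-14). Its musculus day 0 level lies close to 4.76, the limit of the dimmest 25% of genes, so the size of that rise may not be exact. ENSMUSG00000031425 rose in musculus from 8.06 ± 0.62 to 13.24 ± 0.03 and in spretus from 8.63 ± 0.12 to 13.08 ± 0.13. Among falling genes, ENSMUSG00000025789 went from 10.38 ± 0.05 to 6.21 ± 0.16 in musculus and from 10.17 ± 0.23 to 5.93 ± 0.26 in spretus. ENSMUSG00000029510 fell by 4.47 in musculus, from 8.41 ± 0.06 to 3.94 ± 0.26, and by 2.83 in spretus, from 6.64 ± 0.62 to 3.81 ± 0.27. This last gene passed the test of a difference in change given further on.

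Over all genes, the log2 changes from day 0 to day 14 in the 2 species correlated with Pearson's r of 0.90 and Spearman's rho of 0.79, across genes, which are not independent replicates. The root mean square change, after subtracting replicate noise, was 0.57 on the log2 scale in musculus (0.56 to 0.58 with 1 array left out) and 0.53 in spretus (0.53 to 0.54). Of the 1283 genes called in musculus alone, 83.2% changed in the same direction in spretus, and of the 1050 called in spretus alone, 80.7% did so in musculus. A call in 1 species alone is thus not a difference between the species, which was tested separately.

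From day 14 to day 56 fewer genes changed, and by less. In musculus 627 genes rose and 842 fell (11.9% of genes tested), and in spretus 491 rose and 513 fell (8.13%). At least 2-fold changes were seen in 23 rising and 37 falling genes in musculus and in 18 and 17 in spretus. The root mean square change was 0.21 in musculus (0.21 to 0.22 with 1 array left out) and 0.19 in spretus (0.18 to 0.19). The species shared 203 rising and 297 falling genes, against 24.9 and 35.0 for independent lists, and 3 genes were called in opposite directions. The changes in the 2 species correlated across genes with r of 0.55 and rho of 0.42. These counts depend on the spread estimated from all 18 arrays: with the arrays of the contrast alone 746 genes were called in musculus and 645 in spretus. The spretus count of 1004 dropped to 535 without spretus day 14 replicate 2, 627 without spretus day 14 replicate 3, 548 without spretus day 56 replicate 2 and 610 without spretus day 56 replicate 3.

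Among falling genes of this step, ENSMUSG00000052229 had a peak at day 14 in both species. Its log2 level in musculus was 8.14 ± 0.40 at day 0, 10.26 ± 0.05 at day 14 and 8.05 ± 0.05 at day 56, and in spretus 8.72 ± 0.15, 10.34 ± 0.01 and 8.31 ± 0.07 (SD, n = 3). After day 14 it fell by 2.21 in musculus (limma, adjusted p = 6.61e-08) and fell by 2.04 in spretus (adjusted p = 7.66e-08). ENSMUSG00000025270 fell in musculus from 8.63 ± 0.46 to 6.50 ± 0.35 and in spretus from 9.09 ± 0.88 to 7.46 ± 0.08, after a rise from day 0 in both. ENSMUSG00000050063 rose in musculus from 5.34 ± 0.11 to 7.16 ± 0.33 and in spretus from 5.35 ± 0.28 to 6.24 ± 0.31. ENSMUSG00000040380, the other rising gene with a large change, rose by 2.10 in musculus (adjusted p = 0.0266), from 7.56 ± 2.00 to 9.66 ± 0.02. That size rests on musculus day 14 replicate 3, at 5.26, and was 0.95 without it, and the call was lost in 5 of 12 alternative settings.

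Most genes that changed before day 14 were not called again after it. In musculus 1877 genes rose and then were not called, and 2241 fell and then were not called. Spretus had 1993 and 2198 such genes. Of these, 1222 and 1531 were the same genes as in musculus, against 303 and 399 for independent lists. Genes that kept going in 1 direction came next. Rising in both steps were 304 in musculus, 215 in spretus and 119 in both species, against 5.29 for independent lists. Falling in both steps were 358, 200 and 116, against 5.80. A rise followed by a fall was called for 235 genes in musculus, 161 in spretus and 82 in both, against 3.06 for independent lists. A fall followed by a rise was called for 95, 110 and 21 genes, the last against 0.846 for independent lists. Genes first called after day 14 numbered 228 rising and 249 falling in musculus, 166 and 152 in spretus, and 25 and 43 in both. Independent lists would share 3.07 in either direction.

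The steps within a species share the day 14 arrays, which by chance alone pull them in opposite directions. In simulated arrays of unchanged groups the 2 steps correlated with r of -0.50 (covariance -0.00922) and 0 genes were called in both. The observed values were 0.13 in musculus (covariance 0.0193) and 0.08 in spretus (covariance 0.00969). Setting the first step of 1 species against the second step of the other shares no array. Then 231 genes rose in musculus and rose further in spretus, and 342 the other way round, against 96.1 and 120 for independent lists. A fall in both steps was called for 182 and 436 genes, against 112 and 171. A rise in musculus followed by a fall in spretus was called for 152 genes against 100, and a rise in spretus followed by a fall in musculus for 167 against 162. A fall in musculus followed by a rise in spretus was called for 111 against 107, and a fall in spretus followed by a rise in musculus for 56 against 127.

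At day 14 the arrays had covered most of the distance between the newborn and the adult profile. Over 863 genes with at least 2-fold changes from day 0 to day 56 in both species, the median gene had gone 82.4% ± 4.49 of the way in musculus and 85.5% ± 0.976 in spretus (SD, n = 3). The difference of 3.07 percentage points was not larger than the spread between arrays (two-sided exact permutation test, p = 0.3; the smallest p this design allows is 0.1). The 457 rising genes stood at 84.5% ± 4.92 in musculus and 86.4% ± 0.0681 in spretus (exact permutation p = 1), and the 406 falling genes at 80.8% ± 4.06 and 84.6% ± 1.84 (exact permutation p = 0.3). The lowest array was musculus day 14 replicate 1, at 77.5%, and without it the difference was 0.598 percentage points.

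**Figure D2:**
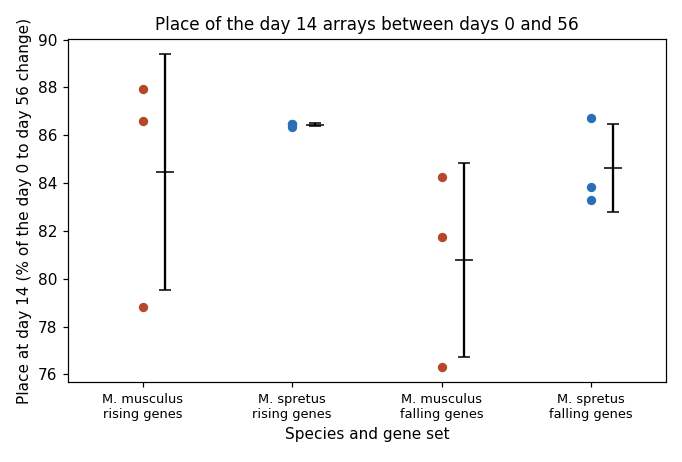
Place of each day 14 array between the day 0 and day 56 means of its own species, in percent of the change (vertical axis, which does not start at 0), for 457 rising and 406 falling genes; points are arrays, and black bars give the mean ± SD of 3 arrays. Musculus replicate 1 is lowest in both sets, and the species overlap in both sets.

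Genes were called between the species at each age. At day 0, 918 genes were higher and 852 lower in spretus; at day 14, 844 and 778; and at day 56, 937 and 828. These are 14.3%, 13.1% and 14.3% of the genes. Differences of at least 2-fold were fewer, with 33 higher and 51 lower in spretus at day 0, 27 and 42 at day 14, and 37 and 42 at day 56. The root mean square difference was 0.24 at day 0, 0.23 at day 14 and 0.24 at day 56, above that between days 14 and 56 within a species and below that between days 0 and 14. The day 14 count of 1622 dropped to 1052 without spretus day 14 replicate 2 and to 993 when its 6 arrays were fitted alone. The balance of the directions depends on the processing. At day 14, 785 genes were higher and 832 lower in spretus after quantile normalization, 484 and 509 with its arrays fitted alone, and 886 and 709 with each array centred on its median, which gave 1042 and 732 at day 56. It also went with masked probes: of the called genes without a masked probe 37.6%, 26.2% and 37.9% were lower in spretus at days 0, 14 and 56, and of those with 7 or more 54.6%, 61.6% and 56.9%. When genes with no masked probe were tested alone, 49, 58 and 80 were called between the species at the 3 ages. From day 14 to day 56, 94 of these genes were called in musculus and 60 in spretus.

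**Figure D3:**
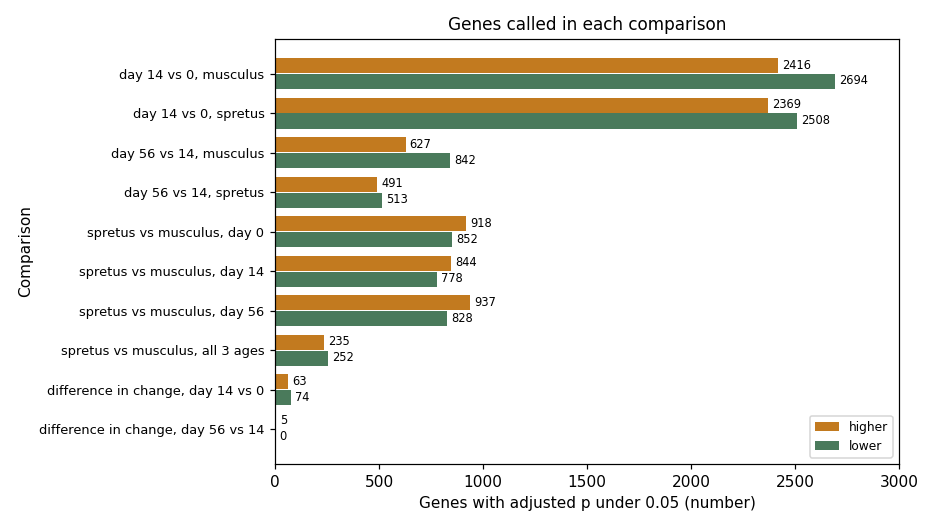
Number of genes called higher (brown) and lower (green) at an adjusted p under 0.05 in each comparison (vertical axis); the first age or species named is set against the second, and the last 2 comparisons are the spretus change minus the musculus change. The bars are longest for day 14 against day 0, with 2416 and 2694 genes in musculus, and shortest for the difference in change from day 14 to day 56, with 5 and 0.

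A part of the species difference was present at all 3 ages. Of 3366 genes called at any age, 2066 were called at 1 age, 809 at 2 and 491 at 3. Of the last, 487 kept 1 direction, 235 higher and 252 lower in spretus, where 3 independent lists would share 4.76 and 3.60. When the arrays of each comparison were fitted alone, 299 genes were called at all ages. The species differences correlated across genes with r of 0.53 between days 0 and 14, 0.51 between days 0 and 56 and 0.63 between days 14 and 56; no array is shared between these. Between days 14 and 56 no gene called at both ages changed direction, and between days 0 and 56, 24 did.

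The genes with the largest difference held over all ages included 2 lower in spretus by 2 or more on the log2 scale at every age. ENSMUSG00000021693 was lower by 3.01 ± 0.18 at day 0 (7.85 ± 0.17 in musculus and 4.83 ± 0.35 in spretus), with log2 differences of -2.49 ± 0.18 at day 14 and -2.45 ± 0.18 at day 56 (SE; limma, adjusted p = 1.43e-08, 1.58e-07 and 1.61e-07). Its spretus levels of 4.83, 4.82 and 4.67 lie near or below 4.76, the limit of the dimmest 25% of genes, so these sizes are not exact. ENSMUSG00000023571 had log2 differences of -2.26 ± 0.11, -2.80 ± 0.11 and -2.60 ± 0.11 at the 3 ages. Higher in spretus were ENSMUSG00000032115, by 2.01 ± 0.17, 1.85 ± 0.17 and 1.53 ± 0.17, and ENSMUSG00000024767, by 1.31 ± 0.12, 1.42 ± 0.12 and 1.82 ± 0.12. The musculus levels of ENSMUSG00000032115 were 4.82, 5.14 and 5.10, the first of them near the same limit, so its sizes may not be exact either. The authors had masked 12 and 16 probes of the first pair of genes and 13 of each of the second pair, against a median of 2 among genes with any masked probe.

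The frequency of species calls rose with the number of masked probes of a gene. Of 3221 genes with no masked probe 0.776% (exact binomial 95% interval 0.503 to 1.14) were called at all 3 ages, and of 1501 genes with 7 or more 13.5% (11.8 to 15.3). Masked probes also went with the level of expression, which had a median of 4.75 on the log2 scale in the former and 8.06 in the latter. Without the genes with 7 or more masked probes, an alternative chosen after the data were seen, 245 genes were called at all 3 ages. Among the 3221 genes without a masked probe, tested alone, 10 were.

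The change from day 0 to day 14 differed between the species in 137 genes, with the spretus change above the musculus change in 63 and below it in 74. Of these, 61 changed in the same direction in both species, 13 in opposite directions, 33 were called with age in musculus alone and 30 in spretus alone. A species difference was called at day 0 alone in 61 of them, at day 14 alone in 54, at both days in 21 and at neither in 1. With the arrays of the contrast fitted alone 62 genes were called, without genes with 7 or more masked probes 83, and among genes with no masked probe 3. Only 99 and 12 of the 137 genes lay in the last 2 sets, so part of each drop comes from the smaller set. Over all genes the count lay between 63 and 204 with 1 array left out. It was 74 without musculus day 14 replicate 3, 78, 77 and 74 without spretus day 0 replicates 1, 2 and 3, and 64 and 63 without spretus day 14 replicates 1 and 2.

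Among the called genes, those with the largest differences in change differed in the age at which the species parted. ENSMUSG00000029510, the falling gene named before, had a species difference of -1.76 at day 0 and was near its day 56 level in both species from day 14 on, and its fall was smaller in spretus by 1.64 ± 0.31 (log2, SE; limma, adjusted p = 0.0142). It was not called when the arrays of the contrast were fitted alone (adjusted p = 0.0587), and its day 14 levels lie below the limit of 4.76 given before, so the sizes of its falls and of their difference are not exact. ENSMUSG00000056966 began at 4.64 ± 0.24 in musculus and 4.38 ± 0.17 in spretus (SD, n = 3) and rose to 6.62 ± 0.14 and 7.97 ± 0.33, a difference in change of 1.60 ± 0.22 (adjusted p = 0.00147); its day 0 levels lie below the same limit. ENSMUSG00000009376 rose by 0.60 in musculus and fell by 0.91 in spretus, from day 0 levels of 6.51 ± 0.18 and 7.73 ± 0.20, and the difference was -1.52 ± 0.19 (adjusted p = 0.0011). ENSMUSG00000030711 rose in musculus from 5.75 ± 0.27 to 7.04 ± 0.61 and stood at 6.17 ± 0.14 and 5.88 ± 0.09 in spretus. Its difference of -1.58 ± 0.37 was just past the threshold (adjusted p = 0.0453) and was not in 13 of 19 alternative settings.

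**Figure D4:**
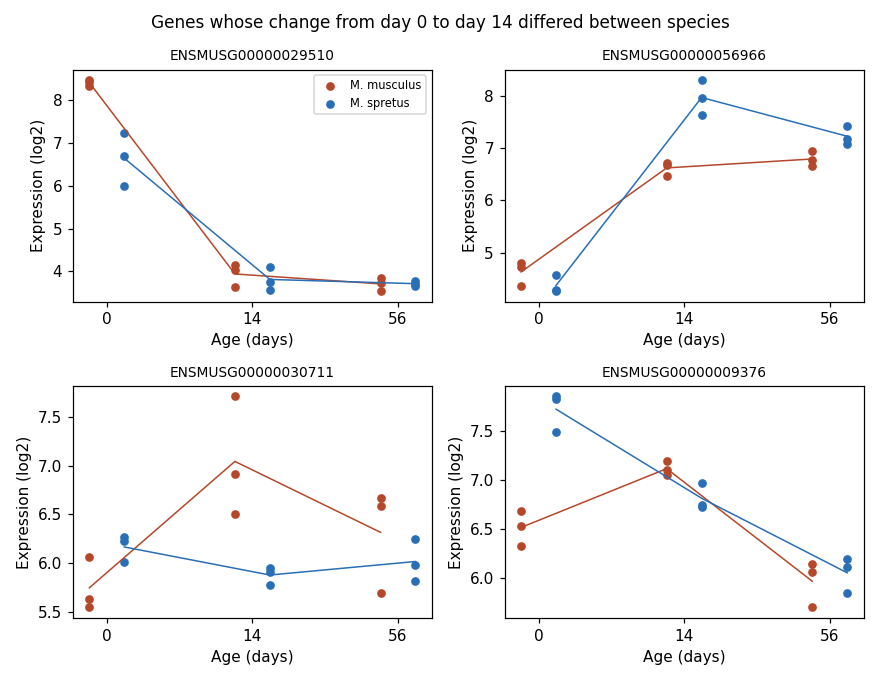
Log2 expression (vertical axes) at days 0, 14 and 56 (horizontal axes, not to scale in time) of the 4 IDs with the largest differences in change from day 0 to day 14, 2 per direction among genes past the threshold; points are arrays and lines join the group means of 3 arrays. ENSMUSG00000029510 differs between the species at day 0 and ENSMUSG00000056966 at day 14.

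Changes from day 0 to day 14 were also compared in size, over genes chosen by the mean change of both species. Of 838 genes with at least 2-fold changes, 530 (63.2%) had the smaller change in spretus, with a median ratio of the spretus to the musculus change of 0.927 (0.907 to 0.956 with 1 array left out). Over all 6159 genes called on the mean change the share was 55.3%, and among those with no masked probe 48.7% in rising and 55.6% in falling genes. The share in the 2-fold set was not larger than other groupings of the arrays gave: 41 of 100 splits of the species labels within the ages lay as far from an even share.

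From day 14 to day 56 the change differed between the species in 5 genes, all with the spretus change above the musculus change. Of these, 3 were also called for the difference in change from day 0 to day 14. Both tests use the day 14 arrays, with opposite signs, so a departure at day 14 can enter both. An unadjusted p under 0.05 (limma) was found for 1328 genes, where a share of 0.05 of the 12346 genes would pass with no difference at all. ENSMUSG00000030560 fell in musculus from 8.61 ± 0.13 to 7.35 ± 0.28 and stood at 6.87 ± 0.21 and 7.04 ± 0.16 in spretus (SD, n = 3), a difference in change of 1.44 ± 0.19 (SE; limma, adjusted p = 0.00525). Its difference in change from day 0 to day 14 was -1.10 (limma, adjusted p = 0.00878). ENSMUSG00000055148 fell by 0.53 in musculus and rose by 0.52 in spretus, with a difference of 1.04 ± 0.15 (adjusted p = 0.00638). The count was 8 without musculus day 14 replicate 1 or 3, 11 without musculus day 56 replicate 1 and 3 without spretus day 56 replicate 1. It was 12 with an intensity trend and robust prior, 3 of them in the other direction, and 1 when the 12 arrays of these ages were fitted alone, where neither of the genes named passed (adjusted p = 0.0607 and 0.0745).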

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

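The tests of probe mismatch by number of masked probes, under other scalings and against genes with a larger change in spretus, of masking within strata of expression level, of other splits for the share of smaller changes, of newborn spretus brains standing closer to later ages, and of other splits from day 0 to day 56 were chosen after the results were seen.

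Differences in change between the species stood out because the test of the difference itself passed. They numbered 137 genes from day 0 to day 14 and 5 from day 14 to day 56, with 3 genes called in both steps. Among these, the largest in each direction from day 0 to day 14 were 1.64 for ENSMUSG00000029510, 1.60 for ENSMUSG00000056966, -1.58 for ENSMUSG00000030711 and -1.52 for ENSMUSG00000009376 (log2, spretus minus musculus change). From day 14 to day 56 they were 1.44 for ENSMUSG00000030560 and 1.04 for ENSMUSG00000055148. Chance in how the arrays fell into groups can be excluded as the source of the whole count of 137 genes, but not of a part of it. With the species labels split anew within the ages, 1 of 100 splits, the real one, gave as many. The highest of the others gave 3. For the second step the splits cannot decide on chance, since the margin was small and mixed splits have lowered counts, as given below. The real split gave 5 genes (1 of 100) and the highest other 3. The count was no more than that without spretus day 56 replicate 1 (3) and with the arrays of the contrast alone (1). For the genes called at all 3 ages the real split gave 487 (1 of 100) and the highest other 0. That the species labels made no difference at all can thus be excluded for this count. How many of the 487 genes chance gave is not shown. The splits concern the counts and not each gene in them. Probe mismatch was not tested for the 137 genes. Of the 137 genes, 61 were called again without spretus day 14 replicate 1 and 58 with the arrays of the contrast alone. Splits that mix the species also put true species differences into the spread between replicates, which lowers their counts. They therefore do not give the number of genes that chance alone would call. For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split gave the most genes in each of them (1 of 10), and the highest other gave 1, 0, 1 and 1 genes in the age steps (musculus and spretus from day 0 to day 14, then both from day 14 to day 56), 5, 0 and 1 between the species at days 0, 14 and 56, and 0 from day 0 to day 56 in either species (5678 genes in the real split in musculus and 5263 in spretus).

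The 487 genes called between the species at all ages may in part reflect the array rather than the brain, since its probes are built for 1 mouse genome and the authors masked some of them. If spretus RNA bound the remaining probes less well, called genes would lean lower in spretus, and over all of them 51.7% did (95% interval 47.2 to 56.3). This share depends on how the arrays are scaled, and the question stays open: it was 54.7% (50.2 to 59.1) after quantile normalization, 48.2% (43.7 to 52.8) after median centring and 59.9% (55.4 to 64.3) after centring on genes with 0 or 1 masked probe within strata of expression level. Among genes with 7 or more masked probes the share as deposited was 60.4% (53.3 to 67.2). It was 62.0% after quantile normalization and 58.9% after median centring, each leaning as such a mismatch needs. With 2 to 6 the share as deposited was 50.2% (43.3 to 57.2) and with 0 or 1 it was 32.9% (22.5 to 44.6). These 2 shares were 52.8% and 40.5% (29.6 to 52.1) after quantile normalization, and 46.2% and 25.7% (16.2 to 37.2) after median centring. Centring on lightly masked genes gave 65.9%, 59.5% (52.6 to 66.2) and 43.7% (31.9 to 56.0), from the most to the least masked set. That centring itself pulls the lightly masked set toward an even share and the others down, so its values, with the 59.9%, cannot decide. Mismatch stays open in both less masked sets, since scaling can push lightly masked genes up when others read low. The intervals are exact binomial ones and treat genes as independent.

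Masking itself went with the calls: 5.06% of genes with a masked probe (4.62 to 5.53) and 0.776% of those without (0.503 to 1.14) were called at all ages. Within 4 strata of expression level, the odds of a call at all ages were 3.75 times as high with a masked probe as without (95% interval 2.51 to 5.61). For a call from day 0 to day 14 in musculus, where no second species enters, they were 1.80 times as high (1.62 to 2.00). The 2 ratios are unlike measures, since the first needs a call in 3 comparisons and the second in 1. Single species calls were not tested within strata. The first ratio fits an effect of the masking, or of what the masked probes mark. Whether such an effect is larger for species calls than for age calls cannot be told from these ratios. The reason for masking is not stated here. Of the called genes 25 had no masked probe, and 10 were called when such genes were tested alone. A true difference in expression between the species stays open for all 487 and was not tested apart from the array.

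The smaller changes from day 0 to day 14 in spretus (63.2% of 838 genes) could come from chance in how the arrays fell into groups, since 41 of 100 splits, the real one included, gave a share as far from 50%, and the farthest of the others lay as far from it as 79.8%. An offset between arrays would make rising and falling genes go apart. The share was above 50% in both, 66.3% in rising and 59.6% in falling genes (54.5 to 64.5, and 54.6 to 64.0 with 1 array left out). An offset alone would not give this, but the interval treats genes as independent, while splits of the arrays gave shares as far from 50%. Among all called genes with no masked probe it was 48.7% in rising and 55.6% in falling genes, and among the 2-fold ones 59.5% and 61.1%. An offset thus stays open. Weaker binding of spretus RNA would put the genes with a smaller change lower in spretus, and 49.2% were (44.9 to 53.6). This is not the majority set beforehand. Among the genes with a larger change in spretus 38.3% were (32.9 to 44.0), so the share was higher where the change was smaller, as weaker binding would have it, and it stays open. That newborn spretus brains stood closer to later ages is a biological explanation: the day 0 species difference would then follow the change from day 14 to day 56. Across genes the correlation was -0.00778, within the size of 0.0660 that other splits reached. This test could hardly decide, since the changes of the 2 steps correlated with r of only 0.08 to 0.28. On component 1 the newborn spretus arrays (-41.1 to -39.4) all lay nearer to the later ages than the musculus ones (-47.5 to -42.9). These scores rest on the same day 0 arrays as the smaller changes and are no separate support. The explanation stays open too.

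The place of the day 14 arrays did not differ between the species by more than the spread. An offset between arrays could still shift it: the difference was 3.86 percentage points in falling genes (1.63 to 5.60 with 1 array left out) and 1.98 in rising genes (-0.830 to 3.72), so that its sign in rising genes is not settled and an offset cannot be told apart from a difference in timing.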

How the results depend on the processing

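Leaving out genes with 7 or more masked probes and centring on genes with 0 or 1 masked probe were chosen after the data were seen; the other settings were fixed before. No ID named changed sign in any setting run, but the difference in place among rising genes ran from -0.830 to 3.72 with 1 array left out, against 1.98. The balance of higher to lower calls turned in these settings. Between the species at day 14 it went from 844 and 778 to 785 and 832 (quantile normalization), 484 and 509 (its arrays alone), 551 and 559 or 569 and 580 (without musculus day 14 replicate 2 or 3) and 506 and 546 (without spretus day 14 replicate 2). At day 0 it went from 918 and 852 to 674 and 700 (without spretus day 0 replicate 1), and at all ages from 235 and 252 to 250 and 233 (median centring), 131 and 114 (under 7 masked probes) and 7 and 3 (no masked probe). In spretus it went from 2369 and 2508 to 2460 and 2439 from day 0 to day 14 (median centring), and from 491 and 513 to 514 and 469 (median centring), 617 and 616 (filter on dim genes) and 328 and 317 (its arrays alone) from day 14 to day 56. For the first difference in change it went from 63 and 74 to 2 and 1 (no masked probe) and 39 and 38 (without spretus day 0 replicate 2). The counts of the 4 age steps and of the species at each age stayed within 1.5 times under repeated quantile normalization, median centring, the filter on dim genes, and the trend and robust prior. The difference in change from day 14 to day 56 was called for 8 genes (7 higher) after quantile normalization and 12 (9 higher) with the trend and robust prior, against 5 (all higher). Centring on genes with 0 or 1 masked probe gave 489 genes at all ages, 196 higher and 293 lower. Fits on the arrays of the contrast alone, with fewer degrees of freedom, called 746 genes (musculus) and 645 (spretus) from day 14 to day 56, 993 between the species at day 14, 299 at all ages, and 62 and 1 for the differences in change (first and second step).

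Genes with no masked probe, a smaller and dimmer set, gave 529 and 511 calls from day 0 to day 14 (musculus, spretus), 94 and 60 from day 14 to day 56, 49, 58 and 80 between the species at days 0, 14 and 56, 10 at all ages, and 3 and 0 for the differences in change. The correlation of age changes was 0.82 (first step) and 0.39 (second) in them; fewer and dimmer genes were tested, and no other cause was tested. Without genes with 7 or more masked probes, counts were 1135 at day 0, 1010 at day 14, 245 at all ages, and 83 and 3 for the differences in change.

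With 1 array left out, counts ranged from 4612 to 4889 and 4321 to 4549 (day 0 to day 14, musculus, spretus), 1021 to 1168 and 535 to 764 (day 14 to day 56), 1227 to 1515, 1052 to 1466 and 1242 to 1427 (species, days 0, 14 and 56), 393 to 442 (all ages), and 63 to 204 and 3 to 11 (differences in change). The correlations ranged from 0.88 to 0.90 and 0.47 to 0.57, and the difference in place at day 14 from 0.598 to 4.99 percentage points. Of the IDs named, ENSMUSG00000030711 missed the threshold in 13 of 19 settings (adjusted p 0.0168 to 0.103), ENSMUSG00000040380 in 5 of 12 (0.00676 to 0.143), and ENSMUSG00000029510 (difference in change), ENSMUSG00000030560 and ENSMUSG00000055148 in 1 each, the fit on the arrays of the contrast alone.

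The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated with r of -0.16 to 0.15, and 7 of 18 arrays correlated best with their own number. With the replicate block, 5087 and 4847 genes were called from day 0 to day 14 and 126 for the first difference in change, and no total moved by over 1.5 times, but the second had 5 genes higher and 2 lower, against 5 and 0. The set tests of the gene lists and their alternatives were not run, since no ID could be matched to a name. Signal over background was not given per probe, so dim genes could not be told from absent ones.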

Other observations

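In the comparison of birth with day 56, whose totals were given above, 2751 genes were higher and 2927 lower at day 56 in musculus. In spretus 2549 were higher and 2714 lower (limma). At least 2-fold changes were seen in 649 higher and 608 lower genes in musculus and in 558 and 511 in spretus. Alternative settings were not run for these counts.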
